A study of Rattus norvegicus with 48 samples.

How the data were processed

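Heart RNA of 48 male rats was measured on 48 single-colour Cy3 oligonucleotide arrays, 1 rat to an array, in a format of 4 arrays to a slide. The rats fell into 12 groups of 4, from 2 strains and 6 antihypertensive drugs, and were 16 weeks old per the labels. Untreated rats are not among the 12 groups, so every drug value is a difference from another drug.

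The authors' scanner files hold 44254 spots, of which 1377 are controls, and 30367 different probes, 1390 of them spotted 10 times. Per the file headers, each spot carries a processed intensity made by Agilent Feature Extraction 10.7.3.1, or 11.5.1.1 for the carvedilol arrays. It is background-subtracted, corrected for trends across and within the array, and not normalized between arrays. The deposited value table holds log2 values of 22513 probes, with array medians between 7.833 and 7.922. How that table was normalized between arrays is not given in the sources used here. Its values correlated with the log2 scanner intensities at r between 0.973 and 0.983 across probes. Its differences between arrays correlated with those after quantile normalization at r between 0.873 and 0.957, over probes that are not independent. The unsubtracted mean signal was missing from the scanner files of the 16 candesartan and carvedilol arrays.

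The log2 of the processed intensity was taken, and the log2 of each array's 75th percentile over non-control probes was subtracted. Spots that the scanner software marked as non-uniform or population outliers were left out, and repeated spots of a probe were averaged. A probe was kept when it was well above background on all arrays of at least 1 group, which left 21168 probes. The 75th percentile ran from 630.0 to 1306 intensity units across arrays. Between 61.4% and 74.6% of probes were well above background on an array, 214 to 646 spots were marked as outliers, and 0 spots were saturated. The standard deviation of the log2 difference between 2 arrays of a group had a lowest value of 0.150 and a median of 0.271 over 72 pairs, so no array was a copy of another.

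Probes were given current gene symbols through a reference gene table of assembly GRCr8, used for names alone. No match was found for 9395 probes. Where a gene had several probes, which held for 2467 genes, the probe with the highest mean over all arrays stood for it. This gave 18476 features, called genes here, of which 12990 carried a symbol.

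All 48 arrays were fitted together with limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8) for reading, as a model of 12 group means with 36 residual and 2.00 prior degrees of freedom. A gene counted as differing at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The comparisons were the strain difference (SHRSP minus WKY) under each drug and its mean over the 5 drugs other than carvedilol. Further comparisons set the 3 drugs of 1 shared scan date against each other within each strain, and tested whether those drug differences differed between the strains. The strain difference under both renin-angiotensin drugs was set against that under amlodipine, hydralazine and chlorothiazide. Each drug of another scan date was set against the mean of the shared date's 3 drugs within a strain. Values after ± are standard errors of the limma fit with 4 arrays per group unless SD is written. Where no array of a group was well above background, only a lower bound is given. It sets the other group's mean against the dimmest signal that passed as well above background on the same arrays, or the arrays' own values where these were higher.

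Gene lists were written from general knowledge before the data were examined. They are fetal and hypertrophy genes, extracellular matrix and fibrosis, renin-angiotensin and aldosterone, adrenergic and cAMP, calcium handling and ion channels, fatty acid oxidation and PPAR targets, oxidative phosphorylation, glycolysis, immediate early genes, heat shock, circadian clock, macrophage and inflammation, lymphocyte, neutrophil and mast cell, MHC class II, MHC class I and antigen presentation, interferon response, endothelial, smooth muscle and pericyte, fibroblast, cardiomyocyte, atrial, adipocyte, erythroid and blood, nerve and mesothelium, cell cycle, NRF2 and xenobiotic, glucocorticoid and metallothionein, hypoxia and angiogenesis, cholesterol synthesis, ribosomal proteins, and genes studied in hypertensive rat strains. Each of the 32 lists was tested with limma's camera, which compares a list with the other genes, at a preset correlation of 0.01, adjusted over the lists of a comparison. It was repeated with an estimated correlation between the genes of a list. The fry test, which asks whether a list's genes move 1 way without comparing them with other genes, was run as an alternative. A list's score on an array is the mean of its genes' centred values.

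The genes named in the text follow a rule fixed before the data were examined. It takes the 8 largest increases and 8 largest decreases among called genes with a symbol whose groups' arrays did not overlap, the largest called members of each list, and 10 heart genes in every comparison on the shared scan date whether called or not. Chance alone separates 4 arrays from 4 with an exact p of 0.0286. The rule gave more genes than fit, its narrowing was set after the data were seen, and a few of its genes are left out of the text. The strain differences of single drugs and the comparisons across scan dates take 3 increases and 3 decreases. Lists that passed camera or held at least 3 called genes take 2.

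The comparisons, the test, the gene lists, the rule for named genes and most of the alternatives were chosen before the data were examined. The alternatives are named in the closing section, and normexp there used an offset of 50. Of these, 4 were added after the data were seen. Other splits of the arrays were fitted in the same way, at most 100 per comparison.

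The limma step was tested on simulated arrays with 18386 genes. For SHRSP enalapril against hydralazine it recovered 70.1% of genes changed 1.5-fold, 80.6% at 2-fold and 93.9% at 4-fold, with 6 false calls. For the mean strain difference it recovered 86.6% at 1.5-fold and 100% at 2-fold and 4-fold, with 13 false calls. With a simulated slide effect and slide as a block the former gave 56.7%, 82.1% and 93.9%, with 17 false calls. Camera called the 1 shifted list and 0 of 31 others, with the preset and with the estimated correlation. The simulated genes varied independently, so this does not test camera on lists whose genes vary together.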

Results

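Hearts of stroke-prone spontaneously hypertensive rats (SHRSP/Izm) and of the normotensive Wistar-Kyoto strain (WKY/Izm) were compared under 6 antihypertensive drugs, with 4 rats in each of 12 groups. The drugs were the calcium channel blocker amlodipine (20 mg/kg/day), the converting-enzyme inhibitor enalapril (20), the vasodilator hydralazine (10), the angiotensin receptor blocker candesartan (5), the thiazide diuretic chlorothiazide (20) and the adrenergic blocker carvedilol (50). Each array held 1 rat's heart RNA. Amlodipine, enalapril and hydralazine shared 1 scan date, with 1 array of each drug on each of 8 slides, and could be compared within slides. The strains lay on different slides there, and each drug kept 1 position in both strains, so drug and position cannot be told apart. Candesartan and chlorothiazide had scan dates of their own that held both strains on each slide. Carvedilol had a separate date and slide for each strain, so strain and slide cannot be told apart under that drug.

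Group means were removed first. On the shared date, 24 array pairs of different groups on 1 slide correlated across genes at a mean r of 0.471 (0.325 to 0.605). There, 216 pairs across slides gave -0.052 (-0.543 to 0.513). Candesartan pairs of 1 slide gave -0.001 to 0.42. The second principal component, with 17.5% of the variance after 21.9% for the first, separated alternate slides within the shared date and the chlorothiazide date. Shared replicate numbers paired strains on 1 slide under chlorothiazide (r 0.358 to 0.508). Across slides they did under amlodipine (0.308 to 0.407) and hydralazine (0.406 to 0.488). Carvedilol (0.0074 to 0.101) and candesartan (-0.268 to 0.153) did not.

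The mean strain difference over the 5 drugs other than carvedilol asked which genes separate the hypertensive from the normotensive heart whatever the treatment. Acox2, an enzyme of bile acid and branched-chain lipid oxidation, was at least 31.2-fold higher in SHRSP (adjusted p = 2.3e-39). Bcl2l15 was at least 16.1-fold higher, Adtrp at least 5.20-fold, Ripply2 at least 5.21-fold and Cbln1 at least 2.44-fold. The potassium channel subunit Kcne1 (3.63 ± 0.10 log2 units), Tex19.2 (3.62 ± 0.09) and Pbld1 (3.33 ± 0.05) were also higher. The alpha-globin gene Hba-a3 was at least 156-fold lower in SHRSP (adjusted p = 8.6e-36), Lgals7 at least 9.53-fold, Klk1c10 at least 5.09-fold, Rims1 at least 5.04-fold and Samd14 at least 3.43-fold. Agtrap, whose product binds the angiotensin II receptor, was lower by -3.90 ± 0.06 (adjusted p = 1.2e-37), as were Btla (-3.85 ± 0.12) and the fatty acid transporter Slc27a2 (-3.25 ± 0.23). In all, 4105 of 18476 genes were higher and 4721 lower in SHRSP. By the scaling on the array's median the split turned to 5652 higher and 3373 lower. Of these 16 genes 14 had no second separate probe, and for Tex19.2 and Btla the second probe differed by 0.04 and -0.27.

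**Figure D1:**
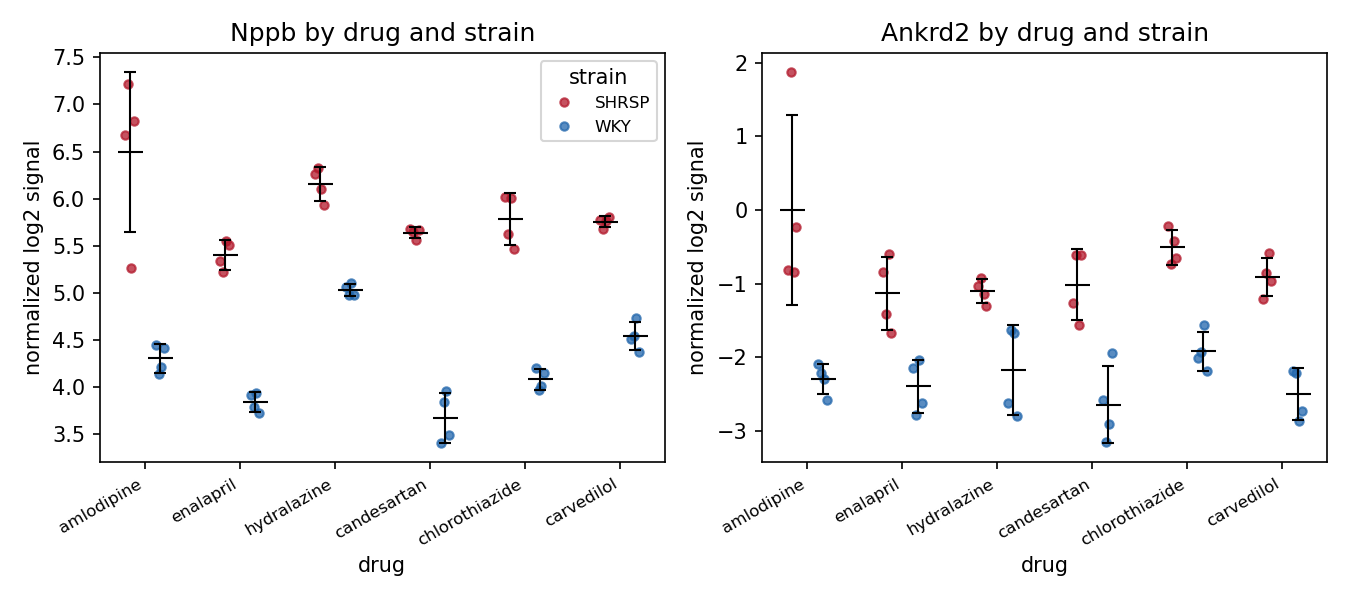
Normalized log2 intensity of Nppb and Ankrd2 on each of 48 arrays by drug and strain, with points for rats and bars for group means with SD. Nppb ran from 3.40 to 7.21 across arrays, and its mean strain difference was 1.71.

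The fetal and hypertrophy genes formed the clearest group of the mean strain difference. Of its 20 genes, 16 were higher in SHRSP and 0 lower (17 and 1 adjusted over the list alone), with a median of 0.56. Nppb differed most (1.71 ± 0.09), followed by Ankrd2 (1.54 ± 0.16), and Nppa, the atrial peptide, was higher by 0.65 ± 0.09. Camera gave adjusted p = 2.2e-10, and adjusted p = 0.14 with an estimated correlation. Every other list call of the mean strain difference was also lost with an estimated correlation (adjusted p = 0.39 to 0.67). Heat shock genes were higher (13 higher, 1 lower, median 0.16, adjusted p = 0.0062), with Hspa1b at 1.07 ± 0.37 and Dnajb4 at 0.63 ± 0.06. Fatty acid oxidation and PPAR targets had 16 higher and 4 lower genes (median 0.08, adjusted p = 0.030), among them the uncoupling protein Ucp2 (0.68 ± 0.05) and Slc27a1 (-0.64 ± 0.04). Glucocorticoid and metallothionein genes had 11 higher and 3 lower (median 0.28, adjusted p = 0.031), led by Fkbp5 (0.76 ± 0.06) and Cebpd (0.76 ± 0.10). Macrophage and inflammation genes had 13 higher and 3 lower (median 0.09, adjusted p = 0.035), with the lysozyme Lyz2 at 0.48 ± 0.04. Oxidative phosphorylation had 17 higher and 3 lower (median 0.07, adjusted p = 0.032), with Ndufa10 at -0.25 ± 0.04. Ribosomal proteins had 13 higher and 1 lower (median 0.06, adjusted p = 0.030), with Rps19 at 0.20 ± 0.03 and Rpl3 at -0.17 ± 0.03.

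Lower in SHRSP as lists were the interferon response, the cell cycle and the genes studied in hypertensive rat strains. Interferon genes had 1 higher and 14 lower (median -0.07, mean -0.19, adjusted p = 0.030). Rig1 was lower by -0.85 ± 0.05 and Ifi44l at least 1.58-fold. Cell cycle genes had 1 higher and 13 lower (median -0.19, adjusted p = 0.031), with the mitotic Birc5 at -0.78 ± 0.11 and Ccnb2 lower at least 1.37-fold. The list of genes studied in hypertensive rat strains had 2 higher and 6 lower (median -0.05, adjusted p = 0.032), with the epoxide hydrolase Ephx2 at -2.35 ± 0.05 and Endog at -2.07 ± 0.03. All 3 were lost (adjusted p = 0.39 to 0.55 with an estimated correlation).

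Other lists did not pass camera. In the mean strain difference 47.8% of all genes differed, so counts alone show little. NRF2 and xenobiotic genes had 9 higher and 2 lower (adjusted p = 0.057), with heme oxygenase Hmox1 at 1.13 ± 0.06 and Osgin1 at 0.66 ± 0.08. Cholesterol synthesis had 8 higher and 2 lower (adjusted p = 0.081), with Insig1 at 0.69 ± 0.04. MHC class I and antigen presentation had 8 higher and 1 lower (adjusted p = 0.081), with RT1-A2 at 0.27 ± 0.08 and B2m at 0.21 ± 0.03. Lymphocyte genes had 2 higher and 11 lower (adjusted p = 0.13), with granzyme Gzma at -0.55 ± 0.07 and Cd79b lower at least 1.03-fold. Immediate early genes had 8 higher and 1 lower, with Myc at 1.11 ± 0.11 and Atf3 at 1.06 ± 0.22. Neutrophil and mast cell genes had 3 higher and 2 lower, among them the mast cell tryptases Tpsab1 (1.21 ± 0.04) and Tpsb2 (0.95 ± 0.05). Adipocyte genes had 3 higher and 7 lower, with the brown fat genes Ucp1 (-3.20 ± 0.90) and Cidea (-1.05 ± 0.04). Renin-angiotensin and aldosterone genes had 1 higher and 3 lower, with angiotensinogen Agt at -0.87 ± 0.19 and Ace at -0.36 ± 0.04. Agt went with fat genes, so fat carried along with hearts may be part of its value. Adrenergic and cAMP genes had 4 higher and 7 lower, with the receptor Adra1d at -2.58 ± 0.11 and the cyclase Adcy5 at 1.05 ± 0.05. Calcium handling and ion channels had 7 higher and 13 lower, with Kcnd2 at -0.58 ± 0.06 and sarcolipin Sln at -0.40 ± 0.13. Lists given without p had adjusted p of 0.14 to 0.44.

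Structural and cell-type lists moved both ways in the mean strain difference. The extracellular matrix had 12 higher and 16 lower of 41 genes (median 0.01), with Ccn2 at 1.24 ± 0.12 and Thbs4 at 1.21 ± 0.07. Fibroblast genes had 6 higher and 8 lower, with Dpt at 1.34 ± 0.03 and Ddr2 at -0.50 ± 0.03. Endothelial genes had 5 higher and 9 lower, with Plvap at -0.86 ± 0.05 and Erg at 0.66 ± 0.04. Smooth muscle and pericyte genes had 2 higher and 5 lower, with Myl9 at -0.26 ± 0.06 and Lmod1 at 0.26 ± 0.07, which turned to -0.01 as the mean of its probes. Cardiomyocyte genes had 7 higher and 3 lower, with Csrp3 at 0.49 ± 0.04 and Hrc at -0.23 ± 0.05. Atrial genes had 4 higher and 5 lower, with Stard10 at -0.95 ± 0.07. Circadian clock genes had 3 higher and 7 lower, with Bmal1 at 1.22 ± 0.09 and Ciart at -1.10 ± 0.15. Glycolysis had 6 higher and 6 lower. Eno1 was lower by -1.55 ± 0.03 and the glucose transporter Slc2a1 higher by 0.61 ± 0.05. Hypoxia and angiogenesis had 6 higher and 7 lower, with Ankrd37 at -0.90 ± 0.07 and Angpt1 at -0.64 ± 0.05. Erythroid and blood genes had 3 higher and 3 lower, with Ahsp at -0.44 ± 0.11 and the transferrin receptor Tfrc at -0.42 ± 0.07. Nerve and mesothelium genes had 4 higher and 3 lower, with Msln at -0.36 ± 0.07. These 11 lists had camera adjusted p values from 0.20 to 0.82.

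Under single drugs the same few genes led the strain difference. Acox2 was higher in SHRSP by at least 62.0-fold under candesartan and 21.6-fold under carvedilol, with the other bounds between. Bcl2l15 was higher by at least 29.6-fold under candesartan and 10.985-fold under amlodipine, with the others between. Hba-a3 was lower by at least 199-fold under candesartan and 92.9-fold under carvedilol, again with the others between. Lgals7 was lower by at least 6.00-fold under amlodipine to 11.6-fold under enalapril, and by -3.89 ± 0.23 log2 units under candesartan, where 1 of 4 SHRSP arrays was above background. Tex19.2 was higher under amlodipine (4.08 ± 0.21) and carvedilol (3.70 ± 0.21), and Rims1 lower under amlodipine by at least 5.14-fold. Adtrp was higher by at least 4.99-fold under enalapril and 3.84-fold under hydralazine. Agtrap fell by 4.27 ± 0.13 under enalapril and Btla by -4.06 ± 0.26 under hydralazine. Under candesartan Oxnad1 was higher by at least 5.52-fold, and Klk1c10 was lower by at least 8.33-fold there and 4.39-fold under chlorothiazide. Kcne1 was higher under chlorothiazide (3.81 ± 0.23), and Slc27a2 lower under carvedilol (-4.36 ± 0.52), with 1 of 4 SHRSP arrays above background.

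Counts of genes differing between strains were 5300 under amlodipine (2216 higher in SHRSP, 3084 lower), 4287 under enalapril (1851, 2436), 3645 under hydralazine (1853, 1792), 3298 under candesartan (1532, 1766), 3202 under chlorothiazide (1793, 1409) and 8537 under carvedilol (4104, 4433). Of these genes 1044 differed the same way under all 6 drugs (509 higher, 535 lower), and 1250 under the 5 without carvedilol. Strain differences correlated across genes at r 0.63 to 0.86 among those 5 drugs and at 0.44 to 0.56 with carvedilol, and genes are not independent replicates. With the replicate number as a block in a fit over the compared arrays, the counts were 1825 under amlodipine, 3204 under hydralazine and 1487 under chlorothiazide. That fit used 8 arrays, of which 6 are paired under chlorothiazide, and without the block the 8 amlodipine arrays gave 1798.

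Fetal and hypertrophy genes were higher in SHRSP under every drug, with medians of 0.60 under amlodipine, 0.45 under enalapril, 0.51 under hydralazine, 0.46 under candesartan, 0.72 under chlorothiazide and 0.80 under carvedilol. Camera gave adjusted p from 9e-13 to 5.2e-06, and adjusted p = 0.059 to 0.42 with an estimated correlation. Matrix genes differed in direction between drugs. The extracellular matrix list was higher in SHRSP under chlorothiazide (21 higher, 0 lower, median 0.35, adjusted p = 7e-06) and carvedilol (20 higher, 3 lower, median 0.34, adjusted p = 0.0043). It was lower under candesartan (7 higher, 17 lower, median -0.20, adjusted p = 0.036). All 3 were lost with an estimated correlation (adjusted p = 0.48, 0.82 and 0.63).

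Enalapril against hydralazine in SHRSP set an inhibitor of angiotensin II formation against a vasodilator that does not block that system. The extracellular matrix genes Cilp (-0.84 ± 0.18), Ccn5 (-0.77 ± 0.14), Ltbp2 (-0.72 ± 0.14), Mfap4 (-0.67 ± 0.12), Lum (-0.54 ± 0.13) and Fbln2 (-0.40 ± 0.08) fell, with adjusted p up to 0.036. Clock genes moved as well: Bmal1 rose by 0.76 ± 0.19 (adjusted p = 0.046), and Dbp (-0.97 ± 0.19, adjusted p = 0.012) and Ciart (-1.28 ± 0.33, adjusted p = 0.049) fell. Genes of fatty acid use rose, namely Angptl4 (1.05 ± 0.25), the uncoupling protein Ucp3 (1.02 ± 0.24) and the kinase Pdk4 (0.74 ± 0.17). The integrin Itgb8 (0.79 ± 0.14), Tectb (0.66 ± 0.16), H19 (0.59 ± 0.13) and Plag1 (0.56 ± 0.12) were also higher, though Itgb8 was -0.0413 under normexp on the mean signal, whose fit of hydralazine rat 13 was distorted. Fam217b (-1.26 ± 0.26, above background on 1 of 4 enalapril arrays), Adh7 (-0.98 ± 0.23), Neu2 (-0.79 ± 0.17) and Fbxl22 (-0.77 ± 0.13) were lower. Skeletal actin Acta1 fell by 0.56 ± 0.11 (adjusted p = 0.013). The SHRSP enalapril against hydralazine values of Nppb (-0.75 ± 0.20, adjusted p = 0.064), Nppa (-0.65 ± 0.20), Col3a1 (-0.47 ± 0.15), Col1a1 (-0.40 ± 0.13), Ace (-0.22 ± 0.09), Adrb1 (-0.21 ± 0.12), Agtr1a (-0.06 ± 0.10), Cacna1c (0.09 ± 0.06) and Myh7 (0.16 ± 0.10) did not pass.

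For SHRSP enalapril against hydralazine limma called 132 of 18476 genes, 62 higher and 70 lower, with slide as a block over all 48 arrays 508, and with slide as a block in the strain's own 12 arrays (6 residual degrees of freedom) 0. In a fit of the 8 arrays alone 0 genes passed, with 2180 at an unadjusted p under 0.05 in the full fit, and leaving out 1 array gave 14 (without hydralazine rat 13) to 122. Quantile normalization gave 47 higher and 31 lower, and median scaling 51 and 21. The extracellular matrix list was lower (3 of 41 genes called lower and 1 higher, 22 and 1 adjusted over the list alone, median -0.26, adjusted p = 4.3e-17, and adjusted p = 0.051 with an estimated correlation), lower on 4 of 4 slides, by -0.37 to -0.17, and with slide as a block adjusted p was 4.3e-13. The fibroblast list was lower likewise (median -0.19, adjusted p = 2.2e-08, and adjusted p = 0.051 with an estimated correlation), on 4 of 4 slides by -0.31 to -0.14. The circadian clock list was lower (median -0.26, adjusted p = 0.0042, and adjusted p = 0.029 with an estimated correlation), on 4 of 4 slides by -0.29 to -0.18, though with slide as a block adjusted p was 0.074, and adjusted p = 0.41 with an estimated correlation. With the block and an estimated correlation the matrix and fibroblast lists also had adjusted p = 0.41. Fatty acid oxidation was higher (median 0.06, adjusted p = 0.00017), on 4 of 4 slides by 0.09 to 0.24. Cell cycle (-0.17, 0.0002), erythroid (-0.16, 0.0042), smooth muscle and pericyte (-0.15, 0.015), hypoxia (-0.15, 0.023), cholesterol (-0.09, 0.049) and, on 3 of 4 slides, macrophage genes (-0.12, 0.041) were lower. These 7 were lost (adjusted p = 0.051 to 0.68 with an estimated correlation). Adipocyte genes went up on 2 slides and down on 2.

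**Figure D2:**
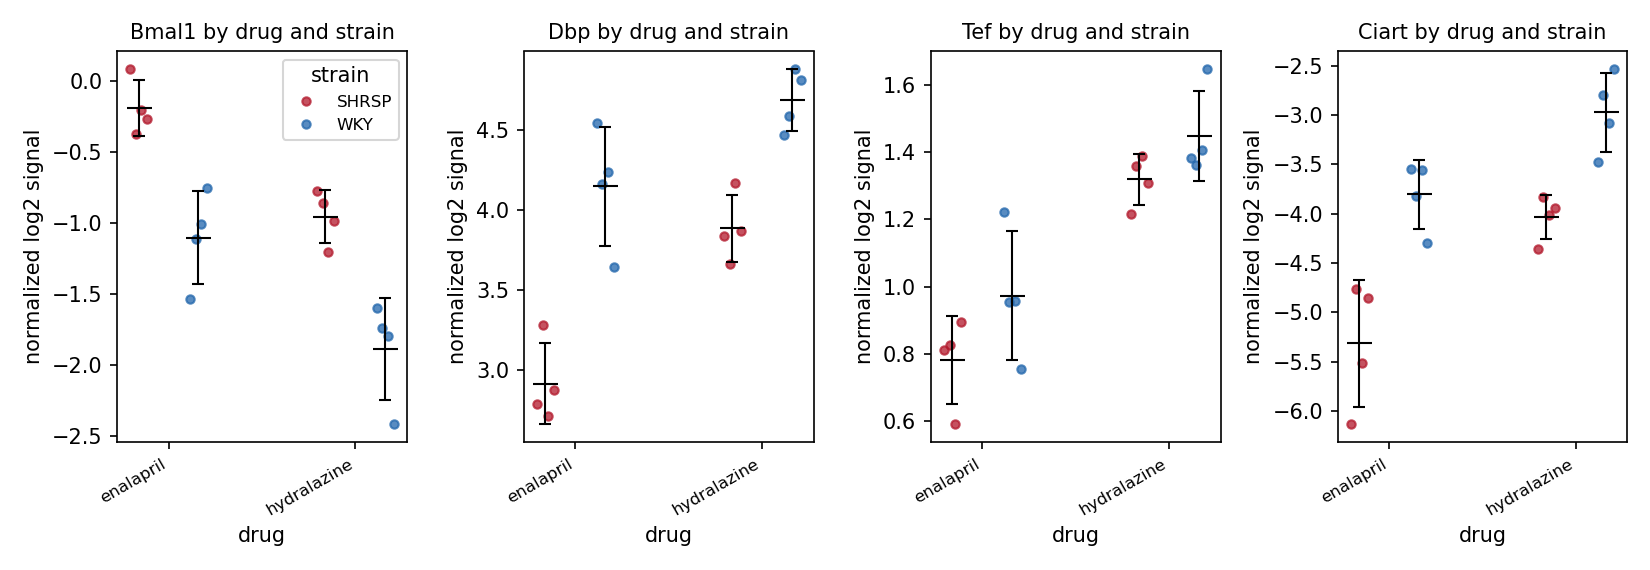
Normalized log2 intensity of the clock genes Bmal1, Dbp, Tef and Ciart on the arrays of the enalapril and hydralazine groups of both strains, with bars for group means with SD. In SHRSP the difference of enalapril from hydralazine was 0.76 for Bmal1 and -0.97 for Dbp.

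**Figure D3:**
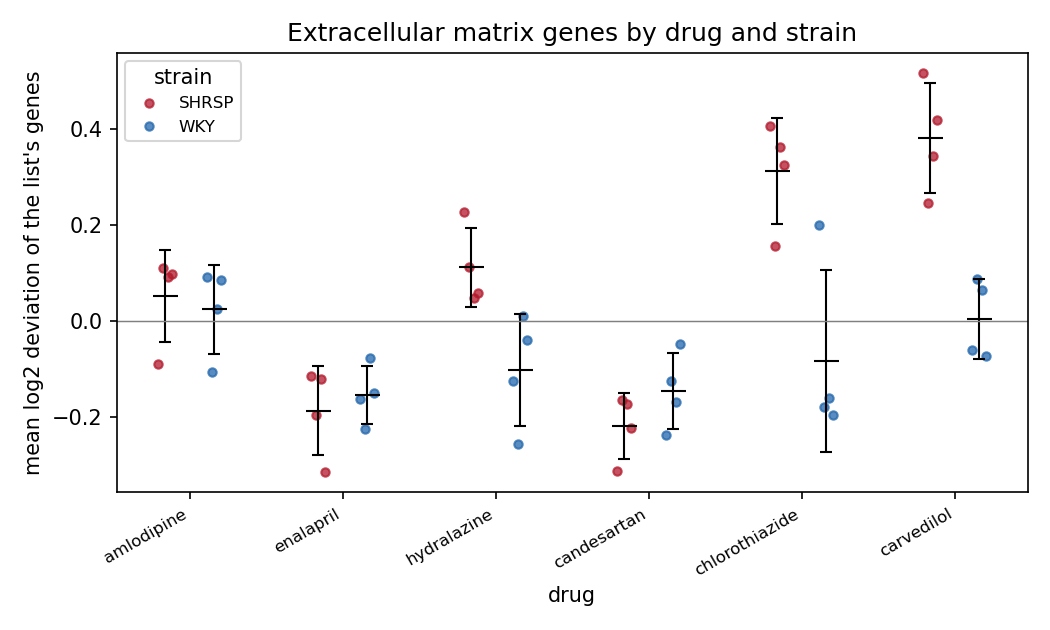
Score of the extracellular matrix and fibrosis list on each of 48 arrays, as the mean centred log2 value of its 41 genes, by drug and strain. SHRSP means ran from -0.22 under candesartan to 0.38 under carvedilol.

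In WKY, Nppb was lower under enalapril than under hydralazine by -1.19 ± 0.20 (adjusted p = 0.00052) and Acta1 by -0.81 ± 0.11 (adjusted p = 3.2e-05), both markers of cardiac load. The vasoconstrictor gene Edn1 was lower by at least 1.46-fold (adjusted p = 0.0090), and the transferrin receptor Tfrc by -0.84 ± 0.16. Angiotensinogen Agt was higher (1.47 ± 0.43, adjusted p = 0.045), by 0.75 ± 0.21 with the adipocyte score as a covariate. Trim21 (1.31 ± 0.29), the neutrophil gene S100a9 (1.26 ± 0.30), Fam161a (1.05 ± 0.19), Depdc7 (1.04 ± 0.14), Rnase1 (1.01 ± 0.19), Slain1 (0.98 ± 0.29) and Ceacam16 (0.95 ± 0.26) were also higher. Trim21 and Slain1 passed background on 1 of 4 hydralazine arrays, and Trim21 turned negative under both normexp corrections, with enalapril rat 5 far above the others. The chemokine Ccl17 (-1.02 ± 0.25), Ocln (-0.97 ± 0.28), Scgb1c1 (-0.90 ± 0.23), Cdhr5 (-0.90 ± 0.15) and C1h11orf86 (-0.86 ± 0.19) were lower. Pdk4 (0.90 ± 0.17), Bmal1 (0.78 ± 0.19), Hmox1 (0.71 ± 0.13) and Mgst1 (0.37 ± 0.11) rose, while Per2 (-0.62 ± 0.17) and the hexokinase Hk1 (-0.41 ± 0.10) fell. The WKY enalapril against hydralazine values of Nppa (-0.38 ± 0.20), Ace (-0.30 ± 0.09), Col3a1 (-0.26 ± 0.15), Agtr1a (-0.23 ± 0.10), Col1a1 (-0.00 ± 0.13), Cacna1c (0.05 ± 0.06), Myh7 (0.09 ± 0.10) and Adrb1 (0.15 ± 0.12) did not pass.

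For WKY enalapril against hydralazine 655 genes differed, 363 higher and 292 lower, 1634 with slide as a block over all 48 arrays, and 91 in a fit of the 8 arrays alone. Median scaling gave 417, and leaving out 1 array 310 (without enalapril rat 5) to 712. Fatty acid oxidation genes were higher (7 of 33 called, 10 higher and 1 lower adjusted over the list alone, median 0.10, adjusted p = 0.016), on 4 of 4 slides by 0.09 to 0.22. The adipocyte list was higher too (0 of 14 called, 2 adjusted over the list alone, median 0.32, adjusted p = 0.020), on 4 of 4 slides by 0.18 to 1.08. Hypoxia (median -0.08, adjusted p = 0.025), fetal and hypertrophy (-0.09, 0.046) and glycolysis genes (-0.07, 0.025) were lower. All 5 were lost (adjusted p = 0.12 to 0.71 with an estimated correlation). Of the enalapril genes, 35 were higher and 35 lower in both strains (1.22 and 1.11 expected by chance) and 0 opposite (r 0.45 across genes). Position on the slide could also give such overlap. No gene passed the test of enalapril against hydralazine by strain with limma (0 of 18476, 524 at an unadjusted p under 0.05). For the 10 fixed genes that test gave values from Nppb at 0.43 ± 0.28 to Col1a1 at -0.40 ± 0.19, and for Adrb1 -0.36 ± 0.18, Nppa -0.27 ± 0.28, Acta1 0.25 ± 0.16, Col3a1 -0.21 ± 0.21, Agtr1a 0.17 ± 0.14, Ace 0.08 ± 0.13, Myh7 0.07 ± 0.15 and Cacna1c 0.04 ± 0.09. The extracellular matrix list fell more in SHRSP than in WKY by this test (median -0.21, adjusted p = 1.9e-10). With an estimated correlation adjusted p was 0.21.

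**Figure D4:**
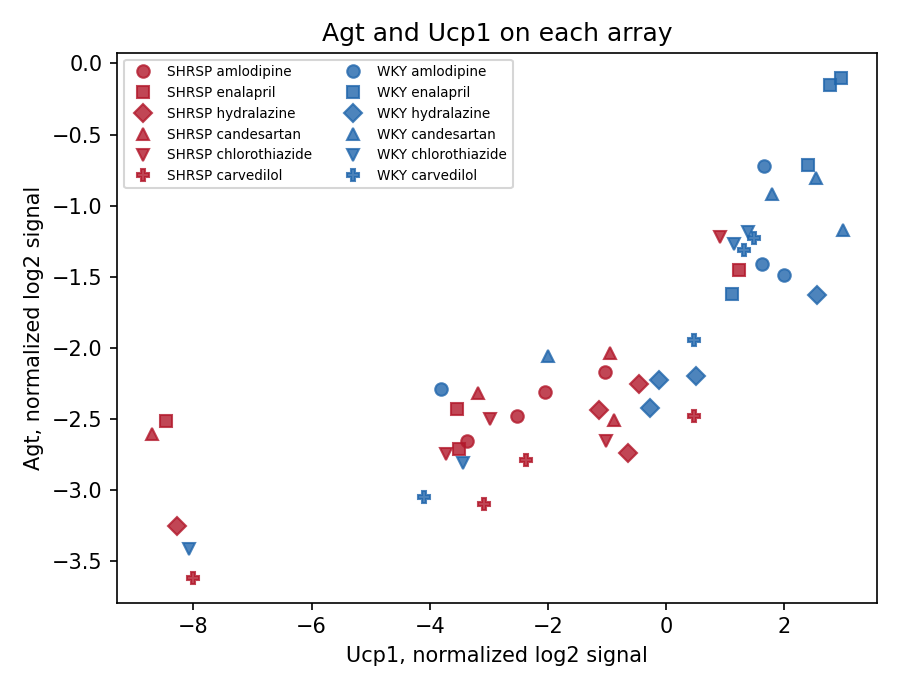
Normalized log2 intensity of Agt against that of the brown fat gene Ucp1 on each of 48 arrays, coloured by strain with 1 symbol per drug. After removal of the group means the correlation over the 48 arrays was 0.80.

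Amlodipine against hydralazine in SHRSP compared 2 vasodilators of different mechanism. The activity-induced nuclear receptors Nr4a2 (-1.84 ± 0.33) and Nr4a1 (-1.59 ± 0.35) were lower under amlodipine, with adjusted p = 0.0039 and 0.015. The vasodilator peptide gene Adm rose by 0.69 ± 0.11 (adjusted p = 0.0014), with the hypoxia gene Ndrg1 (0.70 ± 0.16). Pdk4 (0.84 ± 0.17), Angptl4 (1.07 ± 0.25), Ces2b (0.80 ± 0.20), Gpat3 (0.77 ± 0.17), Il1r2 (0.78 ± 0.21), Tmem108 (0.71 ± 0.13), Map3k6 (0.64 ± 0.16), Enah (0.79 ± 0.15) and Gsta1 (0.27 ± 0.07) were higher. Dyrk3 (-1.37 ± 0.25), Syt17 (-1.23 ± 0.19), endothelial claudin Cldn5 (-0.94 ± 0.19), Mov10 (-0.84 ± 0.21), Ms4a7 (-0.81 ± 0.15) and Lrat (-0.78 ± 0.10) were lower. So were the adrenergic receptor Adra1d (-0.94 ± 0.25), the interferon gene Bst2 (-0.81 ± 0.21), the cytotoxic genes Gzma (-0.69 ± 0.15) and Prf1 (-0.47 ± 0.09), Dhcr7 (-0.51 ± 0.12) and Col15a1 (-0.36 ± 0.09). The highest adjusted p among these was 0.047, for Il1r2, and Mov10 turned higher under the capped normexp. The SHRSP amlodipine against hydralazine values of Col3a1 (-0.53 ± 0.15), Col1a1 (-0.35 ± 0.13), Adrb1 (-0.26 ± 0.12), Nppa (-0.15 ± 0.20), Ace (0.04 ± 0.09), Cacna1c (0.04 ± 0.06), Myh7 (0.07 ± 0.10), Acta1 (0.08 ± 0.11), Agtr1a (0.27 ± 0.10) and Nppb (0.34 ± 0.20) did not pass.

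For SHRSP amlodipine against hydralazine 237 genes differed, 80 higher and 157 lower. Quantile normalization gave 78 and 85, median scaling 85 and 77, and the deposited values 41 and 21. With slide as a block over all 48 arrays 490 genes passed, and 0 with the block in the strain's own arrays. Without SHRSP amlodipine rat 9 the count was 937, and without rat 8 it was 54. The hypoxia list was higher (median 0.07, adjusted p = 0.00029, and adjusted p = 0.0036 with an estimated correlation), on 4 of 4 slides by 0.10 to 0.14, with adjusted p of 0.0091 with slide as a block, and adjusted p = 0.46 with the block and an estimated correlation. Fetal and hypertrophy genes were higher (7 of 20 adjusted over the list alone, median 0.20, adjusted p = 6.2e-06), as were adipocyte (0.17, 0.038), NRF2 (0.07, 0.038) and fatty acid oxidation genes (0.05, 0.017), each on 3 of 4 slides, and glucocorticoid genes (0.20, 1e-05) on 4. Fibroblast (-0.15, 2.5e-05), MHC class I (-0.14, 0.00034) and cell cycle genes (-0.17, 0.00034) were lower, on 4 of 4 slides, as were lymphocyte genes (-0.10, 0.011). Interferon (-0.13, 0.00065) and MHC class II genes (-0.15, 0.022) were lower on 3 of 4 slides, and matrix (-0.13, 0.022) and cholesterol genes (-0.08, 0.048) on 2. All but hypoxia were lost (adjusted p = 0.051 to 0.62 with an estimated correlation).

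In WKY the melanocortin receptor Mc4r was lower under amlodipine than under hydralazine by at least 3.56-fold (adjusted p = 1.6e-05). The RNA of RNase P, Rpph1 (-1.95 ± 0.43), the activity-induced Arc (-1.75 ± 0.24), keratin Krt1 (-1.64 ± 0.24), the atrial potassium channel Kcna5 (-1.40 ± 0.19), the heart-derived hormone C1qtnf9 (-1.40 ± 0.14), Mogat2 (-1.39 ± 0.29), Ly6h (-1.22 ± 0.18) and Sult1a1 (-0.63 ± 0.12) were lower. Krt1 was above background on 2 of 4 amlodipine arrays and Mogat2 on 3. Contactin Cntn2 (1.23 ± 0.25), the adenosine receptor Adora2b (0.75 ± 0.18), Dusp15 (0.71 ± 0.16), Inpp5b (0.63 ± 0.14), Dpep1 (0.61 ± 0.11), the chemokine Cxcl12 (0.59 ± 0.13), mural-cell Notch3 (0.56 ± 0.13), Mcpt1l4 (0.55 ± 0.13) and the collagen cross-linker Lox (0.50 ± 0.12) were higher, with adjusted p up to 0.039. The WKY amlodipine against hydralazine values of Nppb (-0.73 ± 0.20), Myh7 (-0.16 ± 0.10), Cacna1c (0.05 ± 0.06), Agtr1a (0.08 ± 0.10), Nppa (0.09 ± 0.20), Col1a1 (0.10 ± 0.13), Col3a1 (0.10 ± 0.15), Ace (0.14 ± 0.09), Adrb1 (0.19 ± 0.12) and Acta1 (0.25 ± 0.11) did not pass.

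For WKY amlodipine against hydralazine 103 genes differed, 37 higher and 66 lower, against 17 and 71 by quantile normalization, 14 and 74 by median scaling, and 9 and 33 in the deposited table. With slide as a block over all 48 arrays 289 genes passed, and in a fit of the 8 arrays alone 6. Without WKY amlodipine rat 8 the count was 51. Immediate early genes were lower (median -0.31, adjusted p = 9.2e-07, and adjusted p = 0.47 with an estimated correlation), on 4 of 4 slides by -0.63 to -0.35. Smooth muscle and pericyte genes were higher (6 of 17 adjusted over the list alone, median 0.20, adjusted p = 9.2e-07, and adjusted p = 0.11 with an estimated correlation), on 4 of 4 slides by 0.21 to 0.28. Both also passed with slide as a block, where each had adjusted p = 0.0495 with an estimated correlation. Cardiomyocyte (median -0.08, adjusted p = 0.012), oxidative phosphorylation (-0.06, 0.00015), ribosomal (-0.08, 3.5e-05), interferon (-0.11, 0.00024), MHC class I (-0.11, 0.0011) and glucocorticoid genes (-0.09, 0.012) were lower, and matrix (0.10, 0.0030) and cholesterol genes (0.12, 0.012) higher. All 8 were lost (adjusted p = 0.45 to 0.51 with an estimated correlation). The strains shared 2 genes higher and 5 lower, where 0.16 and 0.56 would be expected by chance, and 2 went opposite ways (r 0.12 across genes).

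In SHRSP under enalapril against amlodipine, Nppb fell by 1.09 ± 0.20 (adjusted p = 0.0014, lower on 3 of 4 slides), Acta1 by 0.64 ± 0.11 (adjusted p = 0.00082) and Adm by 0.96 ± 0.11 (adjusted p = 3.6e-06), with Enah (-0.83 ± 0.15) and the oxygen sensor Egln3 (-0.48 ± 0.11). Habp2 (-1.37 ± 0.24), Fam217b (-1.35 ± 0.26), Sox8 (-1.33 ± 0.40), Ccl17 (-1.01 ± 0.25), Hs3st5 (-0.86 ± 0.16), Tmem108 (-0.78 ± 0.13) and Lrrn4 (-0.76 ± 0.21) were lower under enalapril. Habp2 and Fam217b were above background on 1 of 4 enalapril arrays and Sox8 on 3. The macrophage genes Cd163 (-0.68 ± 0.10) and Csf1r (-0.36 ± 0.11), Per2 (-0.62 ± 0.17), Lox (-0.55 ± 0.12), Thbs4 (-0.55 ± 0.15), Tfrc (-0.54 ± 0.16) and the angiotensin receptor Agtr1a (-0.33 ± 0.10) also fell. Eml5 was higher by at least 1.25-fold, Rnf180 by at least 1.82-fold and Mtss2 by at least 1.44-fold, though all 3 turned lower under both normexp corrections. Higher as well were the chemokine Cxcl10 (1.24 ± 0.38), Dyrk3 (1.17 ± 0.25), Cldn5 (0.96 ± 0.19), Ky (0.91 ± 0.24), vasopressin Avp (0.91 ± 0.20), the peptide transporter Tap2 (0.66 ± 0.17), Psmb9 (0.41 ± 0.09), the phosphodiesterases Pde4d (0.63 ± 0.14) and Pde4b (0.59 ± 0.17), Gzma (0.60 ± 0.15) and Prf1 (0.60 ± 0.09). The highest adjusted p was 0.047, for Cxcl10. The SHRSP enalapril against amlodipine values of Nppa (-0.50 ± 0.20), Ace (-0.26 ± 0.09), Col1a1 (-0.06 ± 0.13), Adrb1 (0.05 ± 0.12), Cacna1c (0.05 ± 0.06), Col3a1 (0.06 ± 0.15) and Myh7 (0.09 ± 0.10) did not pass.

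For SHRSP enalapril against amlodipine 836 genes differed, 507 higher and 329 lower. With slide as a block over all 48 arrays 1979 passed, with the block in the strain's own arrays 1, and in a fit of the 8 arrays alone 0. Leaving out 1 array gave 390 (enalapril rat 10) to 1511 (amlodipine rat 9). The hypoxia list was lower (4 of 21 called, 11 adjusted over the list alone, median -0.26, adjusted p = 4e-07, and adjusted p = 3.5e-05 with an estimated correlation), on 4 of 4 slides by -0.33 to -0.15. With slide as a block its adjusted p was 8.5e-05, and adjusted p = 0.16 with the block and an estimated correlation. Fetal and hypertrophy genes were lower (12 of 20 adjusted over the list alone, median -0.32, adjusted p = 2.4e-07), on 3 of 4 slides, and the extracellular matrix (-0.13, 1.8e-06) on 4 of 4 by -0.41 to -0.02. Also lower were clock (-0.20, 0.021) and erythroid genes (-0.15, 0.021) on 4 slides, glycolysis (-0.12, 0.0062) and nerve genes (-0.18, 0.012) on 3 and macrophage genes (-0.12, 0.0095) on 2. MHC class I genes were higher (0.18, 4.3e-05), on 4 of 4 slides by 0.14 to 0.34, with interferon (0.12, 0.0047), lymphocyte (0.11, 0.019) and adrenergic genes (0.09, 0.040). All but hypoxia were lost (adjusted p = 0.10 to 0.55 with an estimated correlation).

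Enalapril against amlodipine in WKY had the largest count of the 6 comparisons on the shared date. Acta1 fell by 1.05 ± 0.11 (adjusted p = 8.7e-08), Edn1 was lower by at least 1.94-fold, and Tfrc (-1.26 ± 0.16), Dpep1 (-1.33 ± 0.11), Kcne1 (-1.27 ± 0.23), Pcdh17 (-1.12 ± 0.17), Ppp1r3g (-1.11 ± 0.30) and Ccl17 (-1.11 ± 0.25) were lower. The pacemaker channel Hcn4 (-0.65 ± 0.13), Thbs4 (-0.72 ± 0.15), collagen Col4a1 (-0.63 ± 0.10), Notch3 (-0.64 ± 0.13), Myl9 (-0.57 ± 0.14), Prph (-0.48 ± 0.12), Hk1 (-0.47 ± 0.10), Uchl1 (-0.45 ± 0.13), Tpsab1 (-0.45 ± 0.10), Ace (-0.44 ± 0.09), Atp6ap2 (-0.36 ± 0.07), Agtr1a (-0.31 ± 0.10) and the glucose transporter Slc2a4 (-0.26 ± 0.08) fell too. Rpph1 (1.93 ± 0.43), Krt1 (1.80 ± 0.24), Fos (1.59 ± 0.54), Lrrc52 (1.58 ± 0.32), Arc (1.51 ± 0.24), Nr4a1 (1.49 ± 0.35), Cldn5 (1.41 ± 0.19) and the chemokine receptor Cxcr4 (1.08 ± 0.20) were higher. Acsm3 passed with 1 of 4 enalapril and 0 of 4 amlodipine arrays above background, and Lrrc52 was above it on 1 of 4 amlodipine and Ppp1r3g on 1 of 4 enalapril arrays. Pdk4 (0.97 ± 0.17), Angptl4 (0.74 ± 0.25), Kcna5 (0.76 ± 0.19), Wt1 (0.70 ± 0.14), Cxcl9 (0.68 ± 0.24), Hmox1 (0.67 ± 0.13), Bmal1 (0.61 ± 0.19), Npas2 (0.58 ± 0.12), Prkar2b (0.51 ± 0.18), Tap2 (0.50 ± 0.17) and Mx1 (0.46 ± 0.15) rose. So did Vwf (0.43 ± 0.09), Kit (0.43 ± 0.15), Gstp1 (0.38 ± 0.06), Tapbp (0.35 ± 0.08), phospholamban Pln (0.33 ± 0.08), Atp5po (0.30 ± 0.09), Mb (0.28 ± 0.07), Cox6a2 (0.28 ± 0.09), Rps23 (0.28 ± 0.07) and Rpl10 (0.25 ± 0.08). Kit, Lrrc52 and Acsm3 turned lower under both normexp corrections. The highest adjusted p was 0.044, for Prkar2b. The WKY enalapril against amlodipine values of Nppa (-0.46 ± 0.20), Nppb (-0.46 ± 0.20), Col3a1 (-0.36 ± 0.15), Col1a1 (-0.10 ± 0.13), Adrb1 (-0.05 ± 0.12), Cacna1c (-0.01 ± 0.06) and Myh7 (0.25 ± 0.10) did not pass.

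For WKY enalapril against amlodipine 2772 genes differed, 1401 higher and 1371 lower, 4323 with slide as a block over all 48 arrays and 1005 in a fit of the 8 arrays alone. Immediate early genes were higher (7 of 22 called, 10 adjusted over the list alone, median 0.66, adjusted p = 6.5e-05, and adjusted p = 0.72 with an estimated correlation), on 4 of 4 slides by 0.45 to 0.98. Ribosomal proteins (median 0.14, adjusted p = 0.0013), MHC class I genes (median 0.20, adjusted p = 0.034) and fatty acid oxidation (median 0.12, adjusted p = 0.038) were higher, and the extracellular matrix lower (median -0.13, adjusted p = 0.0014). The adipocyte list, not past the test (adjusted p = 0.22), was higher on 4 of 4 slides by 0.30 to 0.71. The other 4 were lost (adjusted p = 0.72 with an estimated correlation), and with slide as a block MHC class I (adjusted p = 0.069) and fatty acid oxidation (0.080) no longer passed. The strains shared 228 genes higher under enalapril and 159 lower, where 38.4 and 24.4 would be expected by chance, and 4 went opposite ways (r 0.43 across genes).

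Tests of amlodipine against hydralazine by strain found genes whose drug difference itself differed. Adm (0.98 ± 0.16, adjusted p = 0.0024), Kcna5 (1.55 ± 0.27), Rnf39 (1.33 ± 0.27), Acer2 (1.11 ± 0.15), Fam117b (1.07 ± 0.19), C1qtnf9 (1.04 ± 0.20), Sema6b (1.03 ± 0.14) and Sult1a1 (0.83 ± 0.17) were higher under amlodipine in SHRSP relative to WKY. Mc4r was so by at least 2.85-fold. Dyrk3 (-1.87 ± 0.36), Nalcn (-1.45 ± 0.32), Syt17 (-1.30 ± 0.27), Slitrk6 (-1.12 ± 0.26), Sox4 (-1.01 ± 0.21), Apex2 (-0.82 ± 0.18) and Ptn (-0.81 ± 0.15) were lower. For amlodipine against hydralazine by strain the fixed genes Nppb (1.07 ± 0.28), Myh7 (0.23 ± 0.15), Agtr1a (0.19 ± 0.14), Cacna1c (-0.01 ± 0.09), Ace (-0.10 ± 0.13), Acta1 (-0.16 ± 0.16), Nppa (-0.24 ± 0.28), Col1a1 (-0.44 ± 0.19), Adrb1 (-0.46 ± 0.18) and Col3a1 (-0.63 ± 0.21) did not pass. In all 35 genes differed, 20 up and 15 down, against 22 and 4 by quantile normalization, 26 and 5 by median scaling and 12 and 2 in the deposited table. The count of amlodipine against hydralazine by strain was 430 without SHRSP amlodipine rat 9 and 14 without rat 8, and 0 in a fit of the 4 groups alone. Glucocorticoid genes (median 0.31, adjusted p = 5e-08, and adjusted p = 0.0076 with an estimated correlation), hypoxia genes (median 0.12, adjusted p = 0.0002, and adjusted p = 0.0033 with an estimated correlation) and cholesterol synthesis (median -0.17, adjusted p = 0.00045, and adjusted p = 0.043 with an estimated correlation) differed between the strains.

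Tests of enalapril against amlodipine by strain found 52 genes, 31 up and 21 down. Klk1b3 (1.62 ± 0.35), Dpep1 (1.04 ± 0.16), Rap1gap (0.94 ± 0.22), Arhgap8 (0.89 ± 0.16), Gba3 (0.89 ± 0.15), Hcn4 (0.86 ± 0.18), Fbp1 (0.85 ± 0.16) and Ptn (0.85 ± 0.15) were higher under enalapril in SHRSP relative to WKY. Pdk4 (-1.07 ± 0.23), Tbx1 (-0.96 ± 0.20), Wscd1 (-0.94 ± 0.17), C1qtnf9 (-0.93 ± 0.20), Pbld1 (-0.91 ± 0.16), Adm (-0.88 ± 0.16), Prss12 (-0.87 ± 0.20) and Bnip3 (-0.60 ± 0.14) were lower, and Tmem154 by at least 2.20-fold. The fixed genes of enalapril against amlodipine by strain, Col3a1 (0.42 ± 0.21), Acta1 (0.41 ± 0.16), Ace (0.18 ± 0.13), Adrb1 (0.10 ± 0.18), Cacna1c (0.06 ± 0.09), Col1a1 (0.04 ± 0.19), Agtr1a (-0.02 ± 0.14), Nppa (-0.04 ± 0.28), Myh7 (-0.16 ± 0.15) and Nppb (-0.63 ± 0.28), did not pass. The count fell to 3 in a fit of the 4 groups alone and was 381 without SHRSP amlodipine rat 9. Hypoxia genes differed between the strains (median -0.13, adjusted p = 0.0064, and adjusted p = 0.03 with an estimated correlation). Over all comparisons 7 of 157 list calls held with an estimated correlation, 4 of them in by-strain tests, which were not refitted with slide as a block. The other 3, the clock and hypoxia calls in SHRSP, were lost with the block and an estimated correlation. All these comparisons share groups, so they also share chance.

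The strain difference under enalapril and candesartan, both acting on the renin-angiotensin system, was set against that under amlodipine, hydralazine and chlorothiazide. Matrix genes had a lower strain difference under the renin-angiotensin drugs. They were microfibril Fbn1 (-0.59 ± 0.10, adjusted p = 0.0056) and cross-linker Loxl1 (-0.58 ± 0.12). Others were Col1a1 (-0.56 ± 0.12, adjusted p = 0.023) and Ltbp2 (-0.56 ± 0.13). Prrx2 (-0.61 ± 0.12), Tac4 (-0.59 ± 0.11) and Mcpt10 (-0.58 ± 0.13) were lower. Stk32b (0.83 ± 0.16), Arhgap8 (0.60 ± 0.10), Zfp956 (0.59 ± 0.14), Angpt1 (0.50 ± 0.11), Gba3 (0.49 ± 0.10), Lss (0.47 ± 0.10), Dpep1 (0.46 ± 0.10) and Crym (0.45 ± 0.06) were higher. In all 44 genes differed, 21 higher and 23 lower, against 25 and 15 by quantile normalization and 26 in the deposited table. The count was 15 with the adipocyte score as a covariate, 200 with slide as a random block, and 29 (without WKY candesartan rat 7) to 119 (without SHRSP amlodipine rat 9) with 1 array left out. The extracellular matrix list was lower (4 of 41 called, 16 lower and 1 higher adjusted over the list alone, median -0.23, adjusted p = 3e-18), and so were the fibroblast (-0.15, 4.4e-05), nerve (-0.15, 0.0076), adipocyte (-0.20, 0.0083), ribosomal (-0.06, 0.010), smooth muscle (-0.11, 0.017) and atrial lists (-0.21, 0.0499), with fatty acid oxidation higher (0.01, 0.0499). All 8 were lost (adjusted p = 0.11 to 0.76 with an estimated correlation). The matrix score in SHRSP had means of -0.19 ± 0.09 (SD, 4 arrays) under enalapril and -0.22 ± 0.07 under candesartan, against 0.05 ± 0.10 under amlodipine, 0.11 ± 0.08 under hydralazine and 0.31 ± 0.11 under chlorothiazide. In WKY the means were -0.15 ± 0.06, -0.14 ± 0.08, 0.02 ± 0.09, -0.10 ± 0.12 and -0.08 ± 0.19 in that order. Candesartan and chlorothiazide were scanned apart, so differences of both strains alike drop out of this comparison but date or position effects differing by strain do not.

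Candesartan, chlorothiazide and carvedilol could be set against the 3 drugs of the shared date only across scan dates, so drug and date cannot be told apart in the values that follow. Under candesartan in SHRSP, Synpr was higher by at least 3.94-fold, Pced1b by 2.99 ± 0.39 and the immediate early gene Nr4a3 by 2.84 ± 0.71, while Tp53tg5 was lower by at least 3.69-fold, Sox8 by -1.87 ± 0.32 and Tmem158 by -1.63 ± 0.31. Nr4a3 turned to -0.06 when the filter required signal on all 48 arrays, where another probe stood for it. In WKY, C16h13orf46 was higher (1.41 ± 0.28), with Defb43 at least 1.25-fold and the olfactory receptor Or5p66 at least 1.11-fold higher (both lower under the capped normexp), and Lpal2 (-1.73 ± 0.46), Ppp1r3g (-1.43 ± 0.25) and Eloa2l (at least 3.21-fold) were lower. Under candesartan 4639 genes differed in SHRSP (2089 higher, 2550 lower) and 2963 in WKY (1187, 1776). By median scaling the SHRSP split was 1536 and 3469. The WKY count was 1823 without candesartan rat 7, and SHRSP and WKY counts were 2770 and 1506 with slide as a random block and 7667 and 9408 under the capped normexp. Extracellular matrix genes were lower in SHRSP (median -0.19, adjusted p = 3.2e-05, and adjusted p = 0.75 with an estimated correlation), and immediate early genes higher in both (medians 0.39 and 0.34, adjusted p = 0.003 and 0.03, and adjusted p = 0.75 and 0.95 with an estimated correlation).

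Under chlorothiazide the clock gene Bmal1 was lower in SHRSP (-2.11 ± 0.16, adjusted p = 2.5e-12) and WKY (-2.70 ± 0.16, adjusted p = 9.4e-16), as was Pkib (-2.17 ± 0.47 and -2.96 ± 0.47). In SHRSP Pced1b (2.26 ± 0.39), Rnf126 (2.22 ± 0.40) and Vom1r38 (2.05 ± 0.47) were higher and Oas1e lower by at least 2.07-fold. In WKY Hspa1b (1.70 ± 0.68) and Zbtb16 (1.54 ± 0.21) were higher, Or4k35 by at least 1.58-fold, and the fat hormone gene Retn was lower (-1.85 ± 0.53). The median of all genes was 0.11 in SHRSP and 0.07 in WKY, and 8178 genes differed in SHRSP (5898 higher, 2280 lower) and 6684 in WKY (4308, 2376). Quantile normalization gave 3041 higher and 3986 lower in SHRSP and 2643 and 3454 in WKY, median scaling 3090 and 4102, and 2665 and 3373, and the deposited values 3380 and 2666, and 2831 and 2464. The extracellular matrix list was higher in SHRSP (29 of 41 called higher, median 0.32, adjusted p = 0.0036, and adjusted p = 0.86 with an estimated correlation).

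Under carvedilol in SHRSP, Rnf126 (3.67 ± 0.40), Atxn2l (3.54 ± 0.32) and Tnni2 (3.06 ± 0.26) were higher, and Pkib (-2.75 ± 0.47), Bzw2 (-2.54 ± 0.67) and Or6b13 (at least 1.67-fold) lower. In WKY Slc66a1 was higher by at least 3.02-fold, Lin28b by at least 2.44-fold and Cyp2c22 by at least 2.08-fold, while Nr4a3 (-2.96 ± 0.71), Olr1088 (at least 2.91-fold) and Fancd2osl1 (at least 1.37-fold) were lower. Counts under carvedilol were 9261 in SHRSP (5502 higher, 3759 lower) and 8217 in WKY (4928, 3289), against 2920 and 6197, and 3266 and 4585, by median scaling, and in WKY 3622 and 4616 by quantile normalization. The extracellular matrix list was higher in SHRSP (30 of 41 called higher, median 0.35, adjusted p = 4.1e-05), with the cell cycle (median 0.50, adjusted p = 0.0026) and fibroblast lists (median 0.27, adjusted p = 0.0057), and all 3 were lost (adjusted p = 0.62 with an estimated correlation). Fatty acid oxidation was higher in WKY (23 of 33 called higher, median 0.27, adjusted p = 0.0001, and adjusted p = 0.94 with an estimated correlation).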

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

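The tests on angiotensinogen, the clock genes, the probes and other splits of the arrays were chosen after the results were seen. The search for arrays apart from their group and the tests between strains were not.

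Angiotensinogen Agt was 1.47 ± 0.43 higher under enalapril than under hydralazine in WKY (adjusted p = 0.0452). The layout goes against slide, since each slide held 1 array of each drug and Agt was higher on 4 of 4 slides by 0.57 to 2.27, while the block's 1.47 ± 0.42 (adjusted p = 0.0266) has its size from the layout. With the adipocyte score as a covariate, a test of fat tissue carried along with the heart, it fell to 0.753 (standard error 0.21, adjusted p = 0.0391). Fat carried along may therefore account for part of it, and fat cannot be told apart from a drug effect for Agt, because the score was higher in the WKY enalapril hearts (0.72 ± 0.32, mean and SD) than under hydralazine (0.12 ± 0.31). A drug effect on Agt within the heart or its own fat stays open and was not tested.

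Clock genes differed between enalapril and hydralazine in SHRSP. The layout goes against slide here too. The 4 called clock genes (Bmal1, Dbp, Tef and Ciart) were called with slide as a block over all arrays. In the strain's own arrays none was, and the blocked clock list had camera adjusted p = 0.074. Of 14 tested clock genes, 100% moved as a shift of tissue collection time would have it, those peaking with Bmal1 higher and those with Dbp lower. This decides nothing, since the 2 phase groups were set after the values had been seen and leave out 3 of the 17 clock genes, and Nr1d1 moved by only -0.02. Collection time and a drug effect on the clock cannot be told apart, because the labels give no times.

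Large strain differences of single genes could come from a strain variant under the probe. Of 266 genes with a mean strain difference of at least 2-fold, 37 had a second probe apart from the first. In 64.9% of these (24 genes) the second probe differed the same way by at least 0.5 times as much, and in 32 it differed the same way by any amount. This argues against a variant under the first probe alone for the 24 and leaves it open for the other 13 and for the genes without such a probe. Inherited differences in expression between SHRSP and WKY stay open and were not tested apart from it.

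Counts of other splits include the real one. For the strain differences, 1 of 35 splits gave as many genes, so that chance can be excluded as the whole cause over splits that take no account of pairs. The real counts and the highest other splits were 5300 and 2769 for the strain difference under amlodipine, 4287 and 265 under enalapril, 3645 and 633 under hydralazine, 3298 and 3 under candesartan, 3202 and 762 under chlorothiazide and 8537 and 1045 under carvedilol. For the mean strain difference 1 of 100 did (8826 and 1713). Under carvedilol the real split is also that between 2 slides and dates, so slide is not excluded, and with slide as a random block the count was 5208. Under amlodipine, enalapril and hydralazine each strain had 4 slides of its own, and under candesartan and chlorothiazide each strain had its own positions. Where the replicate numbers paired the arrays, the highest of the other splits that part all pairs (4, or 3 under chlorothiazide) gave 1543 genes under amlodipine, 1 under hydralazine and 1 under chlorothiazide, with 8 such splits too few for a share under 0.05. The highest other splits under amlodipine and chlorothiazide parted 2 pairs, and that under hydralazine parted 0.

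For SHRSP enalapril against hydralazine, 2 of 35 splits gave as many genes (132 and, highest other, 1158), for SHRSP amlodipine against hydralazine 5 of 35 (237 and 1488), and for SHRSP enalapril against amlodipine 2 of 35 (836 and 986). Chance was not excluded for these 3, nor for WKY amlodipine against hydralazine, with 3 of 35 (103 and 1465). Over all 35 splits, which take no account of slide, it can be excluded for WKY enalapril against hydralazine, with 1 of 35 (655 and 9), and for WKY enalapril against amlodipine, with 1 of 35 (2772 and 950). The highest other splits set alternate slides against each other. In SHRSP enalapril against hydralazine and both amlodipine against hydralazine comparisons they called many times the real count, which points to a structure of the arrays by slide. With slide as a fixed block over all 48 arrays the 6 counts were 508, 490, 1979, 289, 1634 and 4323 in the order given. Of the 8 splits that part all 4 slides, as the real one does, the highest others called 1, 99, 362, 0, 0 and 2 genes in that order, with too few splits for a share under 0.05 within slides.

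Tests of the difference between strains by limma called 0 genes for enalapril against hydralazine, with 524 at an unadjusted p under 0.05. Any split gives at least 0, so 100 of 100 (highest other 2) says nothing. They called 35 genes for amlodipine against hydralazine (4 of 100 splits, highest other 1702), 52 for enalapril against amlodipine (4 of 100, highest other 1429) and 44 for the strain difference under renin-angiotensin drugs against other drugs (4 of 100, highest other 1203). The share for these 3 comes from splits that take no account of slide, so it does not exclude chance. The highest called many times more genes and point to a structure of the arrays, and splits within slides were not run. The first of these 3 tests also passed for glucocorticoid and metallothionein (median log2 0.31), hypoxia and angiogenesis (0.12) and cholesterol synthesis genes (-0.17), and the next for hypoxia and angiogenesis genes (-0.13).

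Against the drugs of the shared scan date, 1 of 100 splits gave as many genes in each. Real and highest other counts were 4639 and 2136 for SHRSP candesartan, 2963 and 1529 for WKY candesartan, 8178 and 2149 for SHRSP chlorothiazide, 6684 and 3363 for WKY chlorothiazide, 9261 and 5345 for SHRSP carvedilol and 8217 and 3597 for WKY carvedilol. Chance can be excluded, but the real split is also the split between scan dates, so drug and date cannot be told apart.

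Single arrays stood far from the other 3 of their group in 7 of 96 looks at array measures and list scores (7.29%) and 20 of 373 at genes under the naming rule (5.36%), where chance gives about 1 in 20. By list score, SHRSP hydralazine 16 was low for fetal and hypertrophy genes (0.170) and for adipocyte genes (-0.953). WKY hydralazine 16 was low for fetal and hypertrophy genes (-0.371). For extracellular matrix genes SHRSP amlodipine 7 was low (-0.0903) and WKY chlorothiazide 19 high (0.201). SHRSP amlodipine 9 was low for clock genes (-0.295), and WKY amlodipine 8 for adipocyte genes (-0.440).

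By gene, with log2 intensities, the arrays standing apart in SHRSP were amlodipine 7 for Fam217b (-5.01), amlodipine 8 for Syt17 (-6.74), amlodipine 9 for Avp (-5.53), enalapril 9 for Cilp (-3.33), enalapril 10 for Sox8 (-6.63) and enalapril 12 for Cacna1c (0.22). In WKY they were amlodipine 8 for Col3a1 (3.42), Mogat2 (-7.31), Prkar2b (-2.03) and Tap2 (-0.51), amlodipine 9 for Cldn5 (-0.81), amlodipine 10 for Cxcl12 (3.18), enalapril 5 for Trim21 (-4.44), enalapril 6 for Prkar2b (-1.52) and Tfrc (-1.38), enalapril 7 for Kcne1 (-2.71), Rps23 (6.63) and Slc2a4 (3.49), enalapril 8 for Ppp1r3g (-7.73) and hydralazine 13 for Dusp15 (-4.68).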

How the results depend on the processing

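Slide as a fixed block over all 48 arrays, the order of the slides as a term, the capped normexp on the median signal and the adipocyte score as a covariate were chosen after seeing the data, and the other alternatives before. Signal over background limits dim genes, since 61.4% to 74.6% of probes were well above it. The mean signal is not in the candesartan and carvedilol files, so normexp on it gave no value for comparisons with those groups. That normexp is distorted by bright background spots, with the background fitted at -185.44 on SHRSP hydralazine 13 and -52.048 on SHRSP chlorothiazide 20, against -16.391 or above on the other arrays. Keeping outlier spots, the stricter filter on dim probes, the mean of a gene's probes and the trended robust prior moved no count of called genes by over 1.5 times. Fewer arrays set the spread in the fit over the compared groups alone, in the slide block within a strain and without 1 array, and a minimum fold passes fewer genes. For the other settings the cause was not tested.

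In the order enalapril against hydralazine, amlodipine against hydralazine, enalapril against amlodipine, the reported counts were 132, 237 and 836 in SHRSP and 655, 103 and 2772 in WKY. Counts not given here stayed within 1.5 times. Normexp on the mean signal gave 0, 11 and 27 in SHRSP and 51, 4 and 665 in WKY. The deposited table gave 24, 62 and 368 in SHRSP and 202, 42 and 1740 in WKY. The compared groups alone gave 0, 0 and 0 in SHRSP and 91, 6 and 1005 in WKY. A minimum fold of 1.5 gave 27, 75 and 134 in SHRSP and 97, 32 and 316 in WKY. Slide as a fixed block gave 508, 490 and 1979 in SHRSP and 1634, 289 and 4323 in WKY over all 48 arrays, and 0, 0 and 1 in SHRSP within a strain. As a random block it gave 477, 641 and 1867 in SHRSP and, for the first 2 in WKY, 1499 and 322. The capped normexp gave 55, 95 and 4011 in SHRSP and, for the last 2 in WKY, 31 and 4687. Enalapril against hydralazine counted 78 in SHRSP after quantile normalization, 72 in SHRSP and 417 in WKY after scaling by the median, and 74 and 407 without a filter on dim probes. Amlodipine against hydralazine in SHRSP counted 149 with the order of the slides as a term.

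Strain differences under amlodipine, enalapril, hydralazine, candesartan, chlorothiazide and carvedilol numbered 5300, 4287, 3645, 3298, 3202 and 8537, and the mean strain difference 8826. With a minimum fold of 1.5 they were 1594, 1223, 1085, 1037, 995, 2892 and 1088. Normexp on the mean signal gave 2025, 1926 and 1257 for the first 3 and 1153 for chlorothiazide. The compared groups alone gave 1798 for amlodipine and 1980 for chlorothiazide, the capped normexp 2108 for chlorothiazide, and slide as a random block 5208 for carvedilol.

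Differences between strains were called for 0 genes in enalapril against hydralazine (1 without a filter on dim probes), 35 in amlodipine against hydralazine and 52 in enalapril against amlodipine. The last 2 were 4 and 0 with normexp on the mean signal, 14 and 16 in the deposited table, 0 and 3 in the compared groups alone, 191 and 270 with slide as a random block, 20 and 14 with the order of the slides, and 10 and 20 with the capped normexp. The last was 22 after scaling by the median and 28 at a minimum fold of 1.5. The 44 genes of the renin-angiotensin drugs against other drugs were 26 in the deposited table, 8 at a minimum fold of 1.5, 200 with slide as a random block and 15 with the adipocyte score as a covariate.

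Against the drugs of the shared scan date, SHRSP and WKY counts were 4639 and 2963 for candesartan, 8178 and 6684 for chlorothiazide, and 9261 and 8217 for carvedilol. A minimum fold of 1.5 gave 795 and 380, 1845 and 1255, and 2321 and 1988. Slide as a random block gave 2770 and 1506 for candesartan and 6031 and 4792 for carvedilol. Without a filter on dim probes candesartan counted 9979 and 8729, and carvedilol in WKY 12645. Normexp on the mean signal gave 4202 and 2806 for chlorothiazide, and the capped normexp 7667 and 9408 for candesartan.

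With the replicate number as a block, the strain difference counted 1825 genes under amlodipine and 1487 under chlorothiazide. For enalapril against amlodipine, where 2 numbers are shared and fewer arrays inform it, it gave 0 in SHRSP and 0 in WKY. It moved no other count by over 1.5 times, and of 130 genes under the naming rule with such a fit 86 were no longer called. The other comparisons within the shared date, and enalapril across strains, share fewer than 2 numbers, and those across dates or between strain differences were not blocked by number. Drugs of the shared date are paired by slide, with the block values above, and enalapril across strains by the order of the slides (r 0.466 to 0.513), whose term gave 5037 genes.

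Leaving out 1 array at a time, the strain difference counted 4310 to 5607 genes under amlodipine, 3422 to 4155 under enalapril, 3022 to 3366 under hydralazine, 2651 to 3091 under candesartan, 2596 to 3148 under chlorothiazide, 7693 to 8046 under carvedilol and 8605 to 9014 in the mean. Against the shared scan date it was 3315 to 4803 in SHRSP and 1823 to 3128 in WKY for candesartan, 6844 to 8247 and 4906 to 6719 for chlorothiazide, and 8133 to 9438 and 7181 to 8226 for carvedilol. WKY candesartan against the drugs of the shared scan date counted 1823 without WKY candesartan 7 and 1878 without 8. The by-strain count of enalapril against hydralazine stayed at 0.

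SHRSP enalapril against hydralazine ranged from 14 to 122 genes, with 34, 33 and 38 without enalapril 10 to 12 and 14, 42 and 76 without hydralazine 13, 14 and 16. SHRSP amlodipine against hydralazine ranged from 54 to 937, with 54 and 937 without amlodipine 8 and 9 and 143, 151, 91 and 87 without hydralazine 13 to 16. SHRSP enalapril against amlodipine ranged from 390 to 1511, with 397 and 1511 without amlodipine 8 and 9 and 390 without enalapril 10. WKY enalapril against hydralazine ranged from 310 to 712, with 310, 435, 394 and 371 without enalapril 5 to 8 and 342, 324 and 360 without hydralazine 13 to 15. WKY amlodipine against hydralazine ranged from 51 to 98, with 51 and 59 without amlodipine 8 and 9 and 66, 60 and 60 without hydralazine 13, 15 and 16. WKY enalapril against amlodipine ranged from 2123 to 2530.

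For amlodipine against hydralazine by strain the range was 14 to 430, with 14 and 430 without SHRSP amlodipine 8 and 9, 22 without SHRSP hydralazine 13, 19 without WKY amlodipine 8, and 18 and 14 without WKY hydralazine 14 and 15. For enalapril against amlodipine by strain it was 22 to 381, with over 2 times the reported count without SHRSP amlodipine 7, 26 and 381 without 8 and 9, 24 without SHRSP enalapril 10, 34 without WKY amlodipine 8, and 22 and 34 without WKY enalapril 5 and 7. For the strain difference under renin-angiotensin drugs against other drugs it was 29 to 119, with 112 and 119 without SHRSP amlodipine 7 and 9 and 29 without WKY candesartan 7.

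Some named genes reversed. The 2 versions of normexp used the mean and the capped median signal. In SHRSP enalapril against amlodipine they gave -0.11 and -0.0899 for Eml5, -0.0880 and -0.11 for Rnf180, and -0.13 and -0.15 for Mtss2. In WKY enalapril against hydralazine they gave -0.0022 and -0.0406 for Trim21. In WKY enalapril against amlodipine they gave -0.15 and -0.12 for Lrrc52, -0.12 and -0.14 for Acsm3, and -0.0192 and -0.0195 for Kit. With normexp on the mean signal alone, Itgb8 in SHRSP enalapril against hydralazine was -0.0413. With the capped version alone, Mov10 in SHRSP amlodipine against hydralazine was 0.0267. In WKY candesartan against the drugs of the shared scan date Defb43 was -0.23 and Or5p66 -0.16. With the stricter filter Nr4a3 in SHRSP candesartan against the drugs of the shared scan date was -0.0578, and with the mean of a gene's probes Lmod1 in mean strain difference was -0.0137.

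Of 459 genes under the naming rule, 417 kept direction and side of the threshold after quantile normalization, 427 after scaling by the median, 414 without a filter, 441 with the mean of probes, 459 with outlier spots kept, 455 with the trended robust prior, 287 in the compared groups alone, 386 at a minimum fold of 1.5, 446 with slide as a random block, 374 with the capped normexp and 425 with the adipocyte score. So did 367 of 458 in the deposited table, 344 of 348 with the stricter filter, 167 of 329 with normexp on the mean signal, 253 of 311 with the order of the slides, 135 and 233 of 240 with slide as a fixed block within a strain and over 48 arrays, and 6841 of 7488 without 1 array. Of 157 list results, 7 did with an estimated correlation and 89 with fry, and 48 of 56 with slide as a block.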

Other observations

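This test of Agt and fat genes was chosen after the data were seen. Agt and genes of fat varied together among hearts of the same group. After removal of the group means, Agt correlated over 48 arrays with the brown fat gene Ucp1 at r 0.80 (Spearman 0.84), with adiponectin Adipoq at 0.91 (0.90) and with the amino acid transporter Slc36a2 at 0.84 (0.86). Each permutation p was 1e-05, the smallest the permutations can give, and the adjusted p over 9 relations was 3e-05. Without the 2 arrays farthest from the centre, the 3 values of r were 0.77, 0.90 and 0.82. In WKY alone they were 0.91, 0.94 and 0.85 over 24 arrays, and in SHRSP alone 0.75, 0.86 and 0.83.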
